A study of Homo sapiens with 12 samples.

How the data were processed

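Gene expression was measured on 12 Illumina BeadChip arrays of K562 cells, a human erythroleukemia line. Per the labels' protocols, wild type cells and cells expressing AE9a were nucleofected with 3 µg of a control siRNA or an siRNA against PRMT1. They were harvested after 24 hours, and total RNA was column-purified and copied into biotin-labelled cRNA. Each sample's line, siRNA and replicate number came from its title, which gave 4 groups of 3 arrays. The labels do not say whether the 3 replicates of a group were separate cultures, so p-values measure only the spread between these samples, which may be technical.

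The deposited table of non-normalized values holds 1 intensity per probe and array, with no detection p-value and no control probes. No background had been subtracted from these bead intensities, judged from the values, which stay well above 0. GenomeStudio is named, without a version, in the submitters' processing notes; its role is not given in the sources used here. A further deposited table holds the submitters' processed intensity for the same arrays on a linear scale, normalized between arrays by a method not given in the sources used here. Each of its 12 columns matched its own array best, and Spearman's rho between the levels of the 2 tables was 0.999 or higher for each array. The median of its columns lay between 65.5 and 65.8. Values were on the scale of the raw signal and carried no centring, and no ratio was involved, so no direction stayed open. This table was used only as an alternative.

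Median raw intensity ran from 60.5 to 74.3 across arrays. In place of detection p-values, the 437 probes of olfactory receptor genes, which are hardly transcribed outside sensory tissue, served as a stand-in for background. The 95th percentile of their signal lay between 66.7 and 79.5 per array, and 46.0% of the 47231 probes lay above it on at least 3 arrays. A probe below this level on every array of a group has only a bound there. Its fold is given as "at least N-fold", the brighter group's mean over the dimmer group's mean of, per array, the higher of that percentile and the probe's own signal. The number of arrays limits the precision of each value.

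Probes were named through the platform annotation supplied for this work, of which 30113 probes had 1 gene symbol, 8 had several and 17110 had none. Updating symbols by gene identifier changed 0 names. No gene was named from a probe with several symbols.

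Intensities were corrected with normexp (offset 50) and quantile normalized in limma 3.58.1 under R 4.3.3. The design fixed before the data were examined named neqc where detection p-values existed and this procedure where they did not. Probes whose mean over all arrays lay above the 40th percentile were tested, 28338 in all, standing for 13929 gene symbols; 76.5% of them lay above the olfactory receptor level on at least 3 arrays. Linear models with 1 mean per group were fitted to all 12 arrays with lmFit, and eBayes with an intensity trend gave 13.8 degrees of freedom per probe. All 4 groups thus shared 1 estimate of the spread. Tests were two-sided, with Benjamini-Hochberg adjustment within each of 5 contrasts and a threshold of 0.05. Log2 fold changes are given with their standard error from this model.

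Contrasts were siPRMT1 against control siRNA in each line, the difference of these effects between the lines, and the AE9a line against wild type under each siRNA. Each of 25 gene lists and 4 marker lists fixed before the data were examined was tested in every contrast, 145 tests in one Benjamini-Hochberg family. The test was camera with a preset inter-gene correlation of 0.01 and 1 probe per gene, the brightest over all arrays. Camera with an estimated correlation was run beside it. It called 0 of the 145 tests, against 37 with the preset correlation, so the text gives both p-values for each list call. Counts of list members "adjusted over the list alone" use only the list's own probes for the adjustment. Fry, a rotation test, asked whether a set moved one way on balance.

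Named genes followed a rule fixed beforehand. PRMT1, RUNX1, RUNX1T1, ID1, EGR1 and CDKN1A were always reported. Up to 8 genes with the largest rise and 8 with the largest fall were taken among called genes whose groups did not overlap, leaving out probes without a single symbol and uninformative symbols, and for the difference between lines among all called genes. At most 3 members of each list with the smallest adjusted p were added. Where no gene passed, the 5 genes with the smallest p in each direction were taken as values. Further list members and the metallothionein genes were named after their values were seen, as examples.

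Whether replicate numbers pair arrays was checked from the correlation of same-numbered arrays' deviations from their group means. In wild type cells these were 0.578, 0.283 and 0.536 for numbers 1, 2 and 3, so the numbers paired control and siPRMT1 arrays there. In AE9a cells they were -0.203, -0.296 and 0.000655, and the numbers did not pair them. The pairing comes from the titles' numbers alone.

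The model step was tested on simulated data with 200 of 28338 probes changed. Each line had its own spread, pooled over both siRNA groups and drawn toward the trend with intensity, and same-numbered arrays were not paired. In the simulated siPRMT1 contrast of AE9a cells, 59.7% of changes of 0.5 on the log2 scale were recovered, 97.0% of changes of 1 and 100% of changes of 2, with 7 false calls among 178. In the simulated wild type contrast 61.2%, 98.5% and 100% were recovered, but 95 of 268 calls were false. In the simulated contrast of AE9a against wild type under control siRNA 59.7%, 97.0% and 100% were recovered, with 10 false calls among 181. The median residual SD was 0.133 in wild type arrays and 0.096 in AE9a arrays, so a shared spread understates the error of wild type comparisons that ignore the pairing. On wild type arrays alone, 1251 probes had an unadjusted p under 0.05 for siPRMT1 without a block and 2657 with one. Ignoring the pairing thus enlarges that error, and which way the shared spread errs for the paired comparison is not settled. The list step, run on 13929 genes, recovered a simulated shift of -0.5 in 33 genes in the siPRMT1 contrast of AE9a cells (adjusted p = 5.69e-75, and adjusted p = 3.36e-06 with an estimated correlation), with 0 false calls in 58 unchanged list tests. Simulated genes varied independently of each other. These list results therefore do not show how often the preset correlation gives false calls where genes are correlated.

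Alternatives were no background correction, median scaling, the submitters' values, no filter or a stricter one, no intensity trend, array weights, only the arrays compared, the replicate number as a block, other thresholds, the mean of a gene's probes, estimated correlations, cross-fitting and leaving out each array in turn. Some further alternatives were chosen after seeing the data: filters on the olfactory receptor level, a block in wild type arrays only, fits without both wild type arrays of number 3, and fits on wild type arrays alone with a block or without control 3. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.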

Results

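The series compared 4 groups of K562 cells, each with 3 arrays: wild type or AE9a-expressing cells, each given control siRNA or siRNA against PRMT1 (siPRMT1). AE9a is a splice form of AML1-ETO, the RUNX1-RUNX1T1 fusion protein of acute myeloid leukemia, and PRMT1 is an arginine methyltransferase. The series title poses the question of whether PRMT1 takes part in transcriptional activation by AML1-ETO. The first principal component of the 28338 tested probes held 61.3% of the variance and separated the lines. The second held 15.8% and separated the siRNA groups in AE9a cells. In wild type cells, control 3 scored -15.8 on the second component, near the 3 siPRMT1 arrays (-6.54, -0.454 and -18.0) and away from controls 1 and 2 (21.9 and 21.7).

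**Figure D1:**
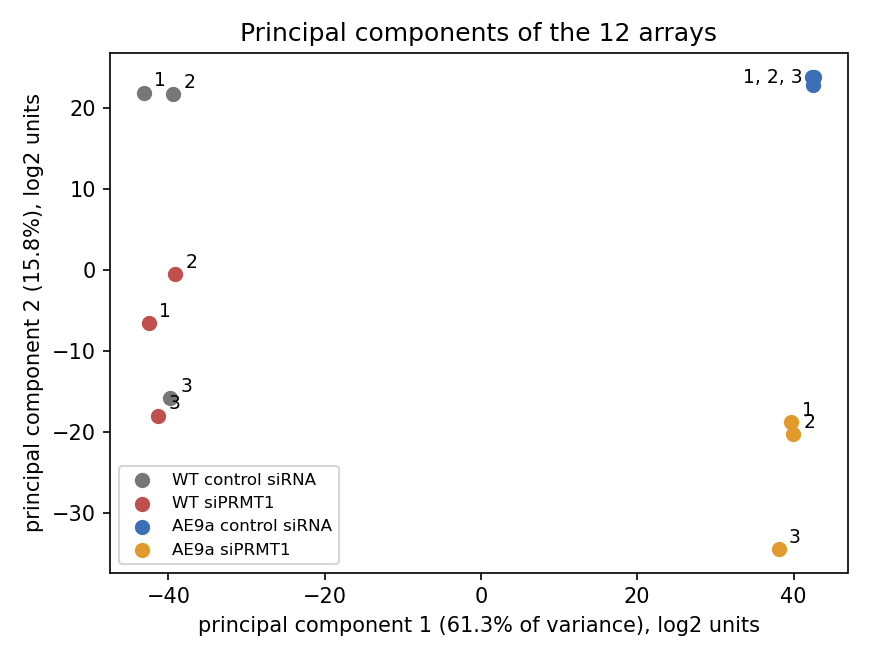
Each point is 1 array, placed by its scores on the first and second principal components of the normalized log2 intensities; colours give the 4 groups and digits the replicate numbers. AE9a arrays lie on the right and wild type arrays on the left, and wild type control 3 lies at -15.8 on the vertical axis, beside the wild type siPRMT1 arrays.

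PRMT1, measured by 1 probe, had a raw intensity of 1446 ± 346 (SD, n = 3) in wild type controls and 1059 ± 190 in wild type siPRMT1 arrays. In AE9a cells it was 768.6 ± 64.5 under control siRNA and 485.0 ± 35.5 under siPRMT1. In AE9a cells PRMT1 fell by 0.61 ± 0.16 (log2 ± SE, adjusted p = 0.021). That call was lost without AE9a control 1 (adjusted p = 0.0653) or 2 (0.0842), or without AE9a siPRMT1 1 (0.0739) or 2 (0.0741). In wild type cells the value was -0.46 ± 0.16 and did not pass (adjusted p = 0.487), and it ran from -0.604 without wild type control 1 to -0.295 without wild type control 3. The array labelled wild type siPRMT1 1 read 1269.7, above the 1166.2 of wild type control 1. The PRMT1 effect was not shown to differ between lines: the difference was -0.14 ± 0.23, with a 95% interval from -0.63 to 0.34. PRMT1 was lower in AE9a than in wild type cells, by -0.89 ± 0.16 under control siRNA (adjusted p = 7.75e-04) and -1.03 ± 0.16 under siPRMT1 (adjusted p = 2.53e-04).

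**Figure D2:**
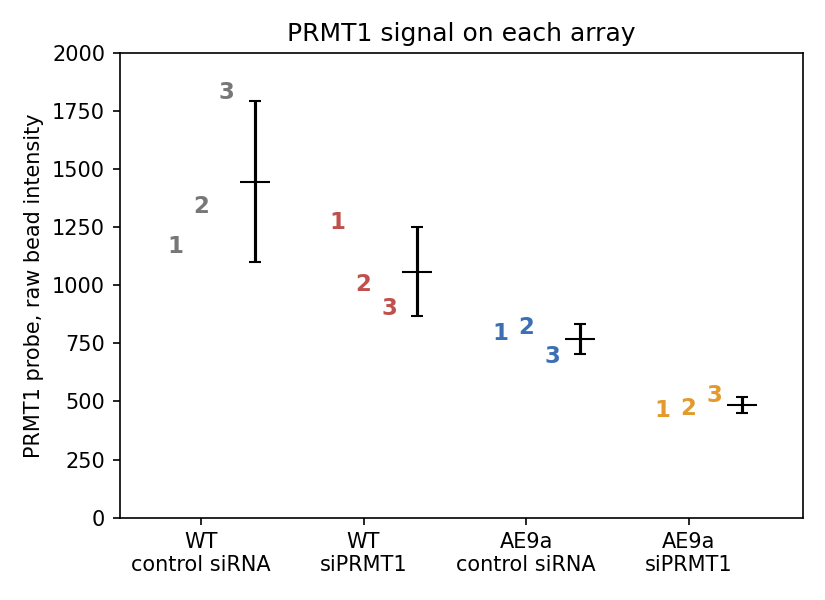
Raw bead intensity of the PRMT1 probe (vertical axis) in the 4 groups; each digit is the array of that replicate number, and the black bar gives the mean with its SD. The AE9a siPRMT1 arrays lie between 461.4 and 525.8 and the AE9a controls between 695.3 and 816.8, whereas the wild type groups overlap.

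Many genes differed between siPRMT1 and control siRNA in AE9a cells. Genes of the integrated stress response fell: DDIT4, an inhibitor of mTORC1 signalling induced by stress, changed by -2.32 ± 0.15, PHGDH, which opens serine synthesis, by -2.31 ± 0.14 and ASNS, asparagine synthetase, by -1.72 ± 0.11. Of 33 measured genes of the integrated stress and unfolded protein responses, 25 fell and 0 rose (26 and 2 adjusted over the list alone). Their median was -0.84 (camera adjusted p = 8.22e-18, adjusted p = 0.387 with an estimated correlation). The transcription factors ATF3 (-1.16 ± 0.21) and DDIT3 (-1.43 ± 0.19) and the tRNA synthetase AARS1 (-1.12 ± 0.10) fell with them. Of the ER chaperones HSPA5, HSP90B1 and CALR in the same list, HSPA5 fell (-0.62 ± 0.18, adjusted p = 0.0302, not recomputed without single arrays). HSP90B1 (-0.17 ± 0.17) and CALR (0.47 ± 0.20) did not pass, and no test compared these genes with each other. Glycolysis and hypoxia genes fell in 17 of 32 measured members and rose in 0 (19 and 0 over the list alone; median -0.49, camera adjusted p = 1.84e-08, adjusted p = 0.406 with an estimated correlation). Among them were the angiogenic factor VEGFA (-1.33 ± 0.13), PGK1 (-0.87 ± 0.17) and PFKL (-0.77 ± 0.12), each by its brightest probe. A further VEGFA probe fell too (-0.82, adjusted p = 4.05e-04). Further probes of PGK1 (-0.50, adjusted p = 0.122) and, at a low signal, PFKL (0.04, adjusted p = 0.767) did not pass.

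Ribosome biogenesis and MYC target genes rose in 22 of 32 measured members and fell in 0 (27 and 1 over the list alone). Their median was 0.66 (camera adjusted p = 1.2e-13, adjusted p = 0.387 with an estimated correlation). The nucleolar proteins NOP16 (1.34 ± 0.18) and UTP20 (0.84 ± 0.12) and the polyamine enzyme ODC1 (0.93 ± 0.13) were the 3 with the smallest adjusted p, whereas MYC itself (0.29 ± 0.13) did not pass. Heat shock genes rose in 14 of 17 members and fell in 1 (16 and 1 over the list alone; median 0.76, camera adjusted p = 2.96e-08, adjusted p = 0.406 with an estimated correlation), among them HSPH1 (1.29 ± 0.23), CHORDC1 (1.25 ± 0.19) and the HSP90 co-chaperone STIP1 (0.76 ± 0.14). HSPA6 was the member that fell by its brighter probe (-0.46 ± 0.12), whereas its dimmer probe rose (0.755, adjusted p = 9.19e-04), so HSPA6 has no single direction. RNA-binding proteins methylated by PRMT1 rose in 7 of 27 and fell in 1 (8 and 2 over the list alone; median 0.23, camera adjusted p = 0.0226, adjusted p = 0.524 with an estimated correlation); SYNCRIP rose (1.22 ± 0.21). EWSR1 fell by its brightest probe (-0.57 ± 0.11), whereas its other probes were at 0.27 and 0.35 and did not pass, so EWSR1 has no single direction. Replication-dependent histones rose in 10 of 41 (12 and 1 lower over the list alone; median 0.19, camera adjusted p = 0.00643, adjusted p = 0.713 with an estimated correlation), H3C4 by 1.30 ± 0.16. That list call was lost without AE9a siPRMT1 1 (adjusted p = 0.066) and, on probes above the olfactory receptor level on all 12 arrays, as was that of the RNA-binding proteins (0.0627 and 0.0625). Of 11 measured arginine methyltransferases and partners 5 rose and 1, PRMT1, fell (5 and 2 over the list alone), with no list call (camera adjusted p = 0.0669). The call of PRMT7, 1 of those 5, was lost without AE9a control 1 (0.0826) or 3 (0.0644) or AE9a siPRMT1 3 (0.101) and under median scaling (0.0575). WDR77, the partner of PRMT5, rose by 1.04 ± 0.11 and PRMT5 by 0.83 ± 0.14.

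Erythroid genes other than hemoglobin chains fell in 12 of 31 members and rose in 2 (the same counts over the list alone; median -0.14, camera adjusted p = 0.0176, adjusted p = 0.524 with an estimated correlation), a call lost on probes above the olfactory receptor level on all 12 arrays (0.0868). SLC25A37, a mitochondrial iron importer, fell by 1.41 ± 0.23 and the blood group gene RHCE by 0.88 ± 0.14. Heme synthesis and iron genes fell in 6 of 22 and rose in 2 (8 and 2 over the list alone; median -0.33, camera adjusted p = 0.0136, adjusted p = 0.406 with an estimated correlation), with CPOX at -1.25 ± 0.23 and UROS at -0.78 ± 0.14. G2/M genes fell in 10 of 30 and rose in 0, also over the list alone (median -0.17, camera adjusted p = 0.00586, adjusted p = 0.601 with an estimated correlation), with the mitotic kinase AURKB at -0.63 ± 0.11. Growth arrest genes fell in 3 of 15 (median -0.18, camera adjusted p = 0.0484, adjusted p = 0.406 with an estimated correlation), 3 also over the list alone, led by RBL2 (-0.93 ± 0.12) and BTG1 (-1.06 ± 0.14). That list call was lost without wild type siPRMT1 1 (0.0535) or 2 (0.0512), AE9a control 1 (0.071) or 2 (0.0599), or AE9a siPRMT1 1 (0.0535) or 3 (0.0729). It was also lost with the submitters' values (0.0535), with array weights (0.0514) and on probes above the olfactory receptor level on at least 3 (0.0693) or all 12 arrays (0.118). Cholesterol synthesis genes fell in 5 of 23 and rose in 1 (6 and 1 over the list alone, median -0.20, camera adjusted p = 0.0415, adjusted p = 0.406 with an estimated correlation), with MSMO1 at -1.07 ± 0.17. A dimmer MSMO1 probe fell too (-1.12, adjusted p = 0.00682), and another did not pass (-0.00, adjusted p = 0.992). The cholesterol list call was lost without wild type control 2 (0.0543) or AE9a control 2 (0.0599), and on probes above the olfactory receptor level on at least 3 (0.0641) or all 12 arrays (0.068).

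In all, 1820 probes (1264 genes) rose and 2093 (1439 genes) fell in AE9a cells after siPRMT1, 862 and 1014 of them by at least 1.5-fold. The largest falls by the naming rule were those of PNCK (-3.32 ± 0.50), INHBE, an inhibin subunit (-2.99 ± 0.24), the metallothioneins MT2A (-2.79 ± 0.34) and MT1X (-2.58 ± 0.61), DDIT4, PHGDH, the transcriptional repressor BCL6 (-2.21 ± 0.13) and ALDOC (-2.13 ± 0.48). The calls of MT1X (adjusted p = 0.0511) and ALDOC (0.0576) were lost without AE9a siPRMT1 3. The largest rises were those of the neurofilament gene NEFH (1.80 ± 0.20), VGF (1.70 ± 0.38), ATP9A (1.48 ± 0.31), GPATCH4 (1.46 ± 0.23), MRPL1 (1.43 ± 0.33), GRWD1 (1.42 ± 0.17), SLC5A6 (1.35 ± 0.18) and NOP16. The kinase gene PIM1 fell by 1.59 ± 0.15 and the death receptor gene TNFRSF10B, by its brightest probe, by 1.57 ± 0.13. A dimmer TNFRSF10B probe fell too (-0.58, adjusted p = 0.00464), and another did not pass (-0.03, adjusted p = 0.867). The count was 2265 without AE9a control 2, 2217 without AE9a control 3 and 2086 without AE9a siPRMT1 3, and with a block in wild type arrays it was 6091. The brighter ID1 probe was at 0.70 ± 0.25 (adjusted p = 0.0873, adjusted p = 0.0475 with the replicate number as a block and 0.012 with a block in wild type arrays). The dimmer ID1 probe was at 0.20 and did not pass (adjusted p = 0.429). Neither CDKN1A nor EGR1 passed. RUNX1 was called higher (0.43 ± 0.13, adjusted p = 0.0464), but the call was lost without wild type siPRMT1 2, any AE9a control, or AE9a siPRMT1 2 or 3 (largest adjusted p = 0.21). It was also lost under median scaling (0.0943) and with the submitters' values (0.0523). Of 78 named genes called here, 62 kept the call without each of the 12 arrays and 16 lost it without at least 1.

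**Figure D3:**
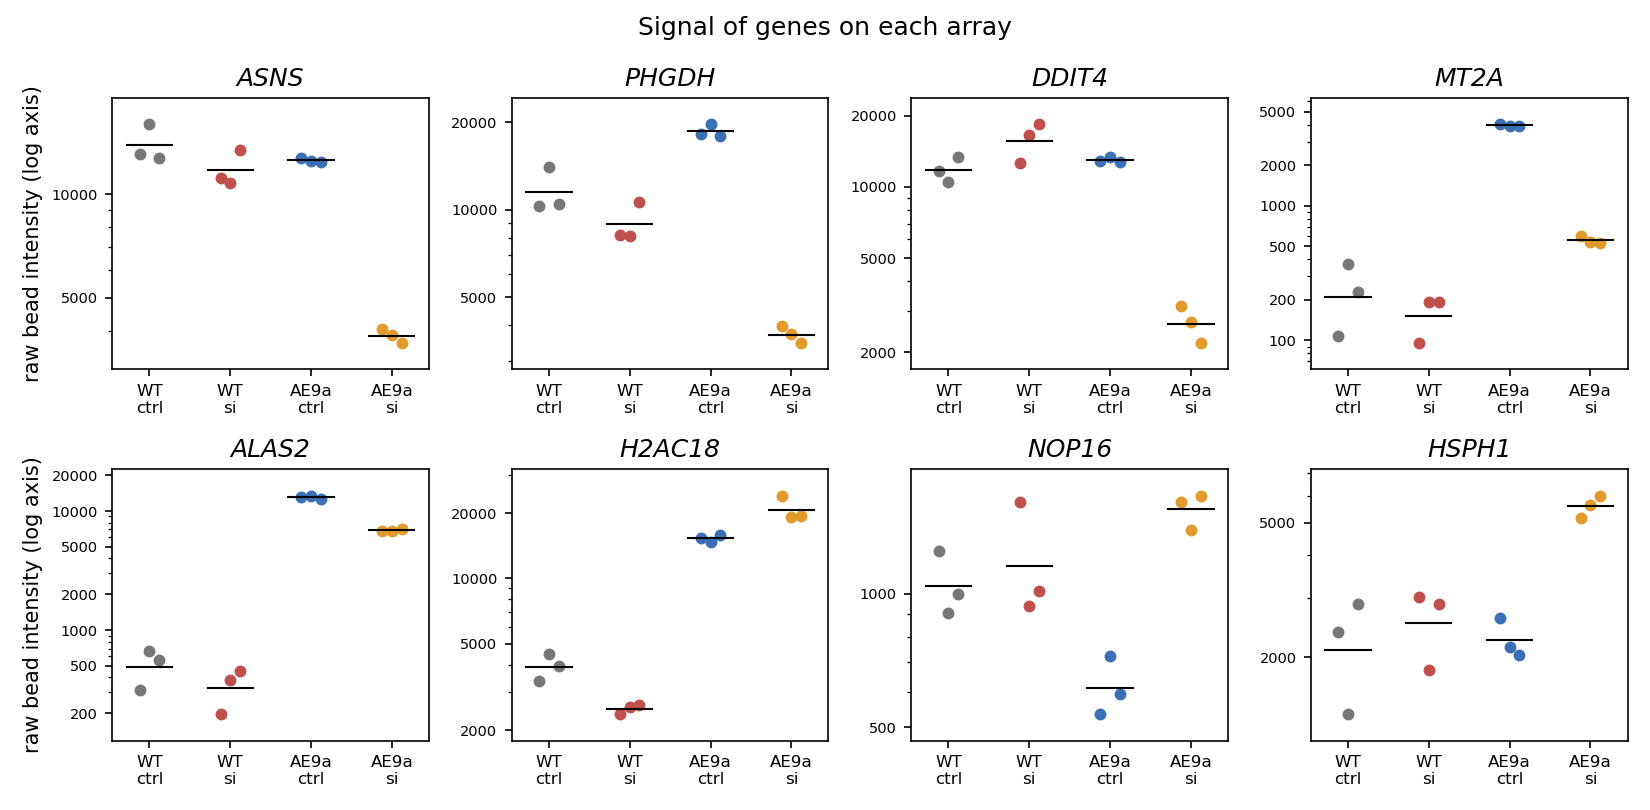
Raw bead intensity (log axis) of 8 named genes on each array, in wild type (WT) and AE9a cells with control siRNA (ctrl) or siPRMT1 (si); points are the 3 arrays of a group, bars their geometric mean. After siPRMT1 in AE9a cells ASNS, PHGDH, DDIT4 and MT2A were lower and NOP16 and HSPH1 higher, and ALAS2 and H2AC18 were higher in AE9a than in wild type cells under both siRNAs.

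In wild type cells no gene passed the test after siPRMT1. limma called 0 probes, with a smallest adjusted p of 0.138, and 2470 had an unadjusted p under 0.05, against 1417 expected by chance. That excess was absent on wild type arrays alone without a block, where 1251 had an unadjusted p under 0.05 and 0 were called. The genes with the smallest p, given as values, included several histone genes: H2AJ (-1.0 ± 0.15) and H2AC20 (-0.82 ± 0.13), both with adjusted p = 0.138, H2AC18 (-0.70), H2AC19 (-0.88) and RABGAP1L (-0.62). Those above 0 were TSPOAP1 (0.36), COBL (0.61), PPHLN1 (0.53), ST8SIA1 (0.32) and SNORA14B (0.35). With a block in wild type arrays 14 probes were called, among them H2AJ and H2AC20 (adjusted p = 0.00809 each), H2AC18 and H2AC19 (0.0123 each) and RABGAP1L (0.0419). With wild type arrays alone and that block 0 were called, and 2657 had an unadjusted p under 0.05. Without wild type control 3, 401 probes were higher and 439 lower. Wild type arrays alone without control 3, a fit that also has fewer degrees of freedom, gave 0 calls, 3489 unadjusted p under 0.05 and a smallest adjusted p of 0.169.

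Camera nevertheless called 7 lists in wild type cells, each with 0 members called over all probes. Ribosome biogenesis genes had a median of 0.14 (adjusted p = 4.84e-05, adjusted p = 0.524 with an estimated correlation) and RNA-binding proteins methylated by PRMT1 a median of 0.20 (0.00352, and adjusted p = 0.413 with an estimated correlation). Heat shock genes had 0.14 (0.0323, and adjusted p = 0.738 with an estimated correlation) and immediate early genes 0.15 (0.0259, and adjusted p = 0.606 with an estimated correlation). Below 0 were erythroid genes (-0.11, 5.46e-04, and adjusted p = 0.406 with an estimated correlation), granulocyte and monocyte markers (-0.12, 0.00274, and adjusted p = 0.387 with an estimated correlation) and histones (-0.12, 9.77e-04, and adjusted p = 0.628 with an estimated correlation). Adjusted over the list alone, 6 histones and 1 granulocyte or monocyte marker were lower and 0 members of the other lists passed. The RNA-binding call was lost without wild type control 1 (0.0707). The immediate early call was lost without wild type control 2 (0.313) or 3 (0.082) or siPRMT1 1 (0.538). The heat shock call was lost without wild type control 1 (0.116) or 2 (0.307) or siPRMT1 1 (0.0739) or 3 (0.337) and with the mean of all probes of a gene (0.062), and the histone call without wild type control 3 (0.609) or both number 3 arrays (0.421). Stress response genes had a median of -0.02 and no call. Without wild type control 3 their median was 0.15 and camera called them higher, with 4 of 33 members higher and 0 lower, 7 and 0 over the list alone (0.0325, and adjusted p = 0.709 with an estimated correlation). Without that array camera also called heme synthesis and iron genes (-0.15, 0.0136, and adjusted p = 0.276 with an estimated correlation), G1/S genes (0.16, 0.0119, and adjusted p = 0.709 with an estimated correlation) and G2/M genes (0.12, 0.0495, and adjusted p = 0.54 with an estimated correlation).

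**Figure D4:**
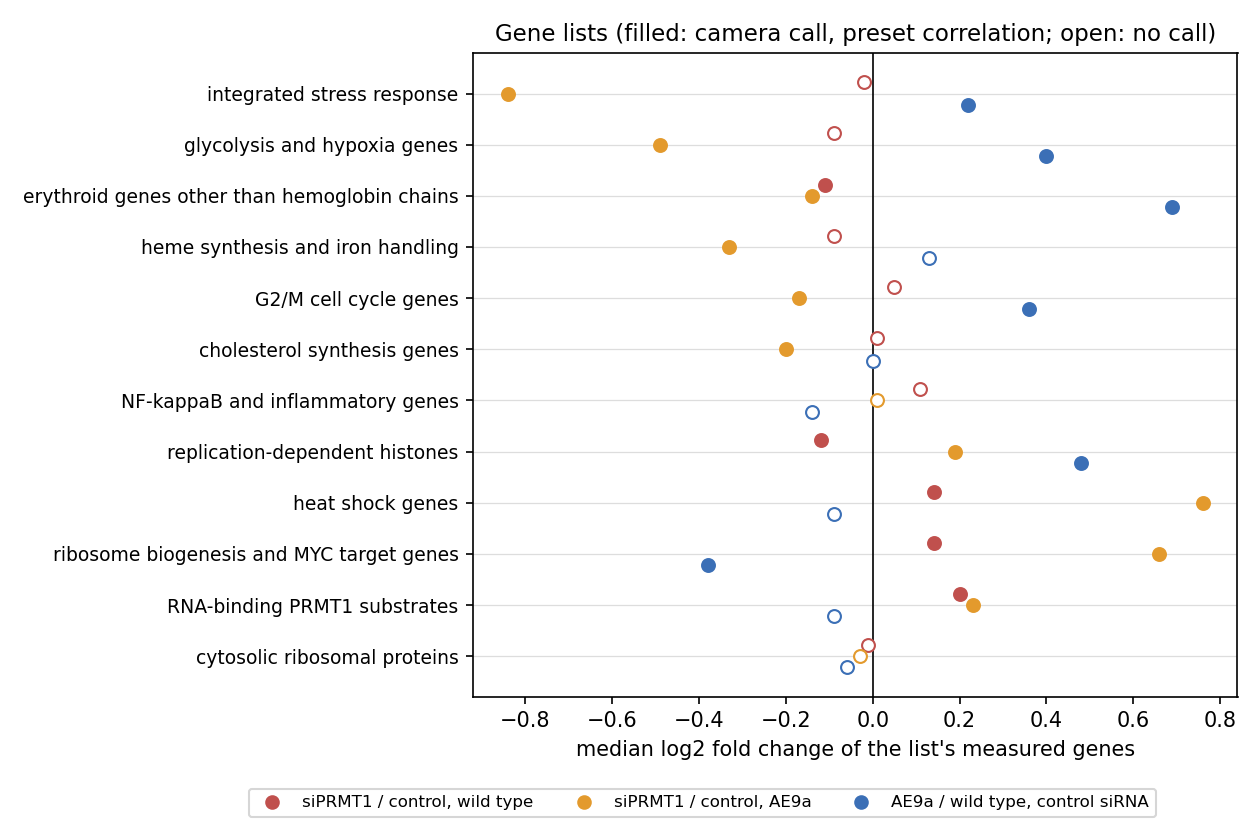
Median log2 fold change (horizontal axis) of the measured genes of 12 lists in 3 comparisons, shown by colour; filled points passed camera with the preset correlation, open points did not, and 0 passed with an estimated correlation. Stress response genes lie at -0.84 after siPRMT1 in AE9a cells and at -0.02 in wild type cells, where they were at 0.15 without control 3.

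siPRMT1 effects in the 2 lines were correlated across probes. Over the tested probes, which are not independent, Pearson's r between the log2 fold changes was 0.454 and Spearman's rho 0.382; the 2 contrasts share no arrays. Without wild type control 2 the r was 0.260. By replicate number the r was 0.251, 0.48 and -0.0155. Of the 3913 probes called in AE9a cells, 81.8% had the same sign in wild type cells. Of the 1820 risers, 319 were also higher in wild type cells at an unadjusted p under 0.05, against 79.0 for independent lists, and 19 were lower, against 79.6. Of the 2093 fallers, 366 were also lower, against 91.6, and 16 were higher, against 90.8.

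The effect of siPRMT1 differed between the lines for 260 probes, 85 (67 genes) more positive in AE9a cells and 175 (118 genes) more negative. Of the lists that camera called for this difference, stress response genes had the most members called. A more negative effect in AE9a cells was called for 16 of 33 members and a more positive one for 0 (24 and 1 over the list alone). Their median difference was -0.93 (camera adjusted p = 1.87e-23, adjusted p = 0.387 with an estimated correlation). DDIT4 differed by -2.75 ± 0.21, the cysteine synthesis gene CTH by -1.93 ± 0.22, PHGDH by -1.91 ± 0.20 and ASNS by -1.48 ± 0.16. INHBE (-3.08 ± 0.33), the metallothionein MT1E (-2.03 ± 0.18) and TNFRSF10B by its brightest probe (-1.52 ± 0.19) also had more negative effects in AE9a cells. Dimmer TNFRSF10B probes were at -0.62 (adjusted p = 0.0969) and -0.09 (adjusted p = 0.775) and did not pass. S100P, above the olfactory receptor level only in AE9a controls, and the metallothionein MT1G, not above it in wild type siPRMT1 arrays, were called in the same direction, with no size given. Histone genes had more positive effects: 6 of 41 members were called in this direction and 0 in the other (12 and 0 over the list alone; median 0.27, camera adjusted p = 2.6e-07, adjusted p = 0.413 with an estimated correlation). Among them were H3C4 (1.43 ± 0.22), H2AC20 (1.32 ± 0.18) and H2AC18 (1.14 ± 0.17), and H2AJ, a histone gene outside the list, differed by 1.61 ± 0.21. H2AC18 and H2AC19 are near-identical copies whose probes may read both.

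Ribosome biogenesis genes (median 0.36; 3 of 32 more positive, 12 over the list alone; camera adjusted p = 3.25e-09, adjusted p = 0.406 with an estimated correlation) and heat shock genes (0.55; 0 of 17 called, 13 more positive and 1 more negative over the list alone; 6.6e-07, and adjusted p = 0.406 with an estimated correlation) had more positive effects in AE9a cells. Glycolysis and hypoxia genes (-0.49; 1 of 32, 7 over the list alone; 2.34e-08, and adjusted p = 0.406 with an estimated correlation), G2/M genes (-0.28; 0 of 30, 3 over the list alone; 8.82e-05, and adjusted p = 0.406 with an estimated correlation) and cholesterol synthesis genes (-0.26; 1 of 23, 3 lower and 1 higher over the list alone; 0.00459, and adjusted p = 0.387 with an estimated correlation) had more negative effects. So had growth arrest genes (-0.18; 1 of 15, 3 over the list alone; 0.0435, and adjusted p = 0.406 with an estimated correlation), a call lost without wild type control 1 (0.0868) or 2 (0.095), wild type siPRMT1 1 (0.0547) or 2 (0.0853), AE9a control 1 (0.0591) or 2 (0.0567), or AE9a siPRMT1 3 (0.0728), and on probes above the olfactory receptor level on at least 3 (0.0641) or all 12 arrays (0.074).

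The number of differing probes depended on the arrays and the model. With the replicate number as a block it was 402 (152 more positive, 250 more negative), and with a block in wild type arrays 1241. It was 94 without wild type siPRMT1 2, 114, 99 and 83 without AE9a control 1, 2 and 3, 143 without AE9a siPRMT1 1 or 2 and 92 without AE9a siPRMT1 3. Of the calls, 32.7% were more positive in AE9a cells, and 11.9% of 320 under median scaling. Of 28 named genes called here, 13 kept the call without each of the 12 arrays and 15 lost it without at least 1, with adjusted p up to 0.139; each of the 12 arrays ended at least 1 of these calls.

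Under control siRNA, AE9a cells differed from wild type cells in 7555 probes, 3747 (2461 genes) higher and 3808 (2557 genes) lower. Erythroid genes were higher: the heme synthesis enzyme ALAS2 by 4.72 ± 0.29, the Rh blood group genes RHCE by 4.19 ± 0.14 and RHD by 3.37 ± 0.11, and the hemoglobin chaperone AHSP by 2.83 ± 0.12. Of 31 erythroid genes 18 were higher and 3 lower (20 and 4 over the list alone; median 0.69, camera adjusted p = 1.66e-05, adjusted p = 0.387 with an estimated correlation); the progenitor regulator LMO2 was lower (-2.17 ± 0.16). Of 9 hemoglobin chains 4 were higher and 0 lower, also over the list alone, with no list call (camera adjusted p = 0.0611), among them HBE1 (2.92 ± 0.11) and HBA1 (1.69 ± 0.15). Replication-dependent histones were higher in 23 of 41 and lower in 0 (25 and 0 over the list alone; median 0.48, camera adjusted p = 2.6e-07, adjusted p = 0.413 with an estimated correlation), with H2AC20 at 2.12 ± 0.13 and H2AC18 at 1.95 ± 0.12. G2/M genes were higher in 13 of 30 and lower in 2 (15 and 2 over the list alone; median 0.36, camera adjusted p = 0.00274, adjusted p = 0.524 with an estimated correlation), with NUSAP1 at 1.06 ± 0.11. Glycolysis and hypoxia genes were higher in 15 of 32 and lower in 2 (17 and 4 over the list alone; median 0.40, camera adjusted p = 0.00643, adjusted p = 0.713 with an estimated correlation), with the glucose transporter SLC2A1 at 1.03 ± 0.10. Stress response genes were higher in 10 of 33 and lower in 2 (11 and 2 over the list alone; median 0.22, camera adjusted p = 0.0415, adjusted p = 0.791 with an estimated correlation); the call was lost without wild type control 1 (0.244) or 2 (0.0809) or AE9a control 2 (0.0599), and on probes above the olfactory receptor level on at least 3 arrays (0.0693). Ribosome biogenesis genes were lower in 16 of 32 and higher in 0 (16 and 2 over the list alone; median -0.38, camera adjusted p = 0.00126, adjusted p = 0.628 with an estimated correlation), with BOP1 at -1.06 ± 0.13; MYC was lower too (-1.19 ± 0.13).

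The largest rises in AE9a over wild type cells by the naming rule were those of PAGE5 (6.87 ± 0.15), VCX3A (6.25 ± 0.15), VCX (6.16 ± 0.18) and VCX3B (6.12 ± 0.15), close paralogs whose probes may read each other, RHOXF2B (at least 31.0-fold), MAEL (at least 28.5-fold), PAGE1 (at least 26.7-fold) and CTAG2 (at least 25.8-fold). The largest falls were those of the noncoding RNA MEG3 (at least 62.3-fold lower), the steroid-metabolizing enzyme AKR1C3 (-5.37 ± 0.12), the RNA-binding protein LIN28A (-3.90 ± 0.24), the chemokine CXCL8 (-3.74 ± 0.15), SLC16A9 (at least 9.31-fold), TDO2 (at least 10.2-fold), ARHGDIB (-3.57 ± 0.23) and LINC00623 (-3.50 ± 0.13). Dimmer probes of RHOXF2B (0.11, adjusted p = 0.293) and LINC00623 (0.01, adjusted p = 0.909) did not pass. Hematopoietic progenitor genes were lower in 6 of 14 and higher in 2 (6 and 5 over the list alone), with no list call (camera adjusted p = 0.441): MYB was lower (-1.20 ± 0.12) and KIT at least 3.0-fold lower. Among markers of other cells, COL1A2 (-3.34 ± 0.13) and S100A6 (-2.50 ± 0.30) were lower and LYZ higher (2.94 ± 0.16). CDKN1A, a reported AML1-ETO target, was higher (1.31 ± 0.33, adjusted p = 0.00778), and ID1 and EGR1 did not pass. Of 16 measured genes reported as activated by AML1-ETO, 3 were higher and 3 lower, and of 14 reported as repressed, 2 were higher and 3 lower, also over each list alone; neither list was called (camera adjusted p = 0.947 and 0.538). RUNX1 did not pass. The brightest of the 5 RUNX1T1 probes read 72.5 ± 2.82 (SD, n = 3) in wild type and 63.4 ± 2.20 in AE9a controls, at the olfactory receptor level, so these probes show no fusion transcript; where they lie relative to AE9a is not given in the sources used here. With 1 line of each kind, the design does not separate the fusion protein from any other difference between the lines. Of the calls 49.6% were higher, and 61.3% under median scaling.

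Under siPRMT1 the lines differed in 7002 probes, 3365 (2212 genes) higher and 3637 (2427 genes) lower in AE9a cells. Histones stood higher, in 31 of 41 members with 0 lower (32 and 0 over the list alone; median 0.87, camera adjusted p = 5.66e-14, adjusted p = 0.387 with an estimated correlation), and H2AC20 differed by 3.44 ± 0.13. Erythroid genes were higher in 19 of 31 and lower in 4 (19 and 5 over the list alone; median 0.64, camera adjusted p = 1.67e-05, adjusted p = 0.387 with an estimated correlation) and hemoglobin chains in 5 of 9 with 0 lower, also over the list alone (median 0.57, camera adjusted p = 0.0138, adjusted p = 0.49 with an estimated correlation). Heat shock genes were higher in 8 of 17 and lower in 2 (9 and 2 over the list alone; median 0.36, camera adjusted p = 0.0127, adjusted p = 0.662 with an estimated correlation), with HSPA1A at 2.29 ± 0.26. Stress response genes were lower in 21 of 33 and higher in 5 (23 and 5 over the list alone; median -0.71, camera adjusted p = 8.25e-06, adjusted p = 0.515 with an estimated correlation), with STC2 at -3.01 ± 0.18 and DDIT4 at -2.62 ± 0.15. The largest rises again held PAGE5 (6.55 ± 0.15), VCX3B (6.13 ± 0.15), VCX3A (6.04 ± 0.15), VCX (at least 60.2-fold), CTAG2 (at least 40.4-fold), RHOXF2B (at least 34.4-fold), PAGE1 (at least 33.2-fold) and MAGEA1 (at least 26.9-fold). The largest falls were MEG3 (at least 44.3-fold), AKR1C3 (at least 41.3-fold), CXCL8 (at least 15.1-fold), COL1A2 (at least 14-fold), COBL (at least 11-fold), SLC16A9 (at least 10.9-fold), LINC00623 (-3.72 ± 0.13) and LIN28A (-3.57 ± 0.24). RUNX1 was higher (0.45 ± 0.13, adjusted p = 0.0221), a call lost without wild type siPRMT1 2 (0.0562) or 3 (0.0867) or AE9a siPRMT1 2 (0.0537) or 3 (0.108). CDKN1A was at 0.74 (adjusted p = 0.122; adjusted p = 0.0352 with a block in wild type arrays) and EGR1 did not pass. The brighter ID1 probe did not pass (0.44, adjusted p = 0.245), whereas the dimmer one was higher (0.52, adjusted p = 0.014).

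Probes higher in AE9a controls were more often called lower than higher after siPRMT1 in these cells. The 3747 probes higher in AE9a controls had a median siPRMT1 change of -0.145 ± 0.0105 (SD over 3 siPRMT1 arrays, all below 0), against 0.00366 in wild type cells. RHCE and the metallothionein MT2A moved this way: MT2A was 4.19 ± 0.34 higher in AE9a controls and fell by 2.79 ± 0.34 after siPRMT1. Of the 3747 probes, 974 were called lower after siPRMT1, against 277 for independent lists, and 200 higher, against 241. The 3808 probes lower in AE9a controls had a median of 0.0813 ± 0.0194; 609 rose, against 245, and 148 fell, against 281. AE9a control arrays enter both contrasts with opposite sign, so part of the overlap may come from them. With genes chosen on 2 AE9a control arrays and the effect measured against the third, the medians were -0.146 (from -0.165 to -0.118 over the 3 choices) and 0.0707. The covariance of the 2 contrasts across probes was -0.0442, against -0.011 in simulated arrays without effects, a difference of -0.0333. Their correlation was -0.278, against -0.499 in the simulated arrays; without effects the shared arrays alone set its size, so the correlations do not compare effects. The median difference between the lines was -0.158 for raised probes and 0.126 for lowered probes. Fry called this difference for both sets, but not for lowered probes under median scaling, where their median difference was 0.046. Wild type control arrays also enter both the choice of genes and that difference, which moves these medians in the observed direction. Without wild type control 3 the median of the lowered probes in AE9a cells was 0.042.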

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

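The tests on the PRMT1 level of wild type control 3, on the number 3 pair, on culture state and variation between arrays, on knockdown strength and on the shared AE9a control arrays were chosen after their results or the pattern had been seen. The results in the next paragraph stand here because the siPRMT1 effect differed between AE9a and wild type cells by a test of the difference itself, which called 260 probes.

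Stress response genes had a median difference of -0.93, with DDIT4 at -2.75, CTH at -1.93, PHGDH at -1.91, ATF3 at -1.50 and ASNS at -1.48. Glycolysis and hypoxia genes had a median of -0.49 with VEGFA at -1.05, cholesterol synthesis genes -0.26 with SCD at -0.65, growth arrest genes -0.18 with RBL2 at -0.88, and G2/M genes -0.28 with 0 members called. Histones had a median of 0.27, with H3C4 at 1.43, H2AC19 at 1.37, H2AC20 at 1.32 and H2AC18 at 1.14, and H2AJ, outside the list, was at 1.61. Ribosome biogenesis genes had 0.36, with NOP16 at 1.24, RRP9 at 0.89 and UTP20 at 0.77, and heat shock genes had 0.55 with 0 members called. Among other genes, INHBE differed by -3.08, the metallothioneins MT2A by -2.40, MT1E by -2.03 and MT1G by -1.85, S100P by -1.96, TNFRSF10B by -1.52 (brightest probe only), PIM1 by -1.13, UROS by -0.93 and ITGA2B by -0.67. NEFH differed by 1.27, the noncoding RNA RN7SK by 1.09 and CAV1, on the list of reported activated targets, by 0.84. The sizes for S100P, at the olfactory receptor level in all groups but AE9a controls, for CAV1, at that level in both wild type groups, and for MT1G and ITGA2B, at it in wild type siPRMT1 arrays, are fitted values and no measure of the difference. The calls of ATF3, CAV1, H2AC19, ITGA2B, MT2A, NEFH, NOP16, PIM1, RBL2, RN7SK, RRP9, SCD, UROS, UTP20 and VEGFA were each lost without at least 1 array, with adjusted p up to 0.139. Under median scaling NOP16 (0.0628), RN7SK (0.079), NEFH (0.0867) and RRP9 (0.101) were not called, and with the submitters' values MT2A (0.0516), RN7SK (0.0631) and NEFH (0.0516) were not.

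Chance is not excluded for the count of 260, but these splits are a poor measure of it: of 100 of the 200 possible splits of the siRNA labels within both lines, 13 gave at least as many calls, and the highest other gave 5219. Of the other 12 splits that reached 260, 11 kept the AE9a labels and changed only wild type labels, and all 11 drawn splits of that kind reached it; they still hold the siRNA effect in AE9a cells and do not show what chance gives. Of 88 splits that changed the AE9a labels 1 did, with 313 calls, but these mix that effect into the spread within groups, so they do not exclude chance either. A split that calls many more genes than the real one may reflect the structure of the samples. The siRNA effect in AE9a cells stays in those splits while the wild type labels are mixed or exchanged. Structure among the wild type arrays may add to it, since within wild type cells the highest other split gave 433 calls. The share of each was not tested. Exchanging only the wild type siRNA labels gave 3308.

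Stress response genes fell after siPRMT1 in AE9a cells, whereas their median in wild type cells was -0.02, and 0.15 with a camera call (adjusted p = 0.0325, adjusted p = 0.709 with an estimated correlation) without wild type control 3, the wild type array with the highest level of these genes. Normalization is argued against, since the median difference stayed between -0.98 and -0.92 under the 3 other scalings. A culture state that also varies between wild type arrays stays open, since the level of the list spanned 0.44 over these arrays, against a median change of -0.84 in AE9a cells. AE9a controls lay at 0.17, 0.26 and 0.21 and AE9a siPRMT1 arrays at -0.71, -0.69 and -0.61, a gap of at least 0.78. The list was flagged for this same fall, so a gap above 0.44 restates the fall and argues against no cause. Such a state would have to be larger than among wild type arrays and shared by all 3 AE9a siPRMT1 samples. The design does not separate that from the siRNA. A stronger knockdown in AE9a cells could not be told apart from a response that needs the fusion protein, because the 95% interval of the PRMT1 difference runs from -0.63 to 0.34, and a response to PRMT1 loss that depends on the AE9a line may stand beside it, as a hypothesis.

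Of 3747 probes higher in AE9a controls, 974 were called lower and 200 higher after siPRMT1 in these cells, and the median change was -0.145. Variation of single AE9a control arrays is argued against as the whole cause, since the highest of the 3 cross-fitted medians was -0.118. A state common to all 3 AE9a control arrays would pass this test unchanged and stays open. A change that goes with brightness is argued against too: 3740 probes matched on mean intensity and not called between the lines had a median of 0.016. The values may reflect a need for PRMT1 in part of the expression that sets AE9a cells apart, a hypothesis found and tested on the same data. A shift of AE9a siPRMT1 arrays for another reason, such as an off-target effect of the siRNA, was not tested.

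Wild type control 3 decides the wild type count, which was 0 with it and 840 without it. Whether that array holds RNA of siPRMT1-treated cells stays open. Its PRMT1 level lay 0.61 above the highest wild type siPRMT1 array (SD 0.31 among the wild type controls, itself included), although this rests on 1 probe. That probe did not separate the wild type groups: siPRMT1 1 and control 1 were both at 10.22. Over the 427 probes called without both number 3 arrays, control 3 lay a median of 0.66 from controls 1 and 2, toward siPRMT1. The siPRMT1 arrays lay at 0.71, 0.64 and 0.69. Both wild type arrays of number 3 do share a shift (r = 0.536 between their deviations, across probes, and 19.8 and 27.2 on the third principal component). Whether that shift alone sets the count stays open. Over the 427 probes called without these arrays, the median change was 0.67 in pairs 1 and 2. Within pair 3, where a shift common to both arrays cancels, it was 0.02, with 52.7% of the same sign. The probes and signs were chosen on pairs 1 and 2, which enlarges the 0.67. False calls among these probes would also give little change within pair 3, so the test does not decide. A state of the control 3 cells alone was not tested and stays open. The 840 calls may include many false ones, since wild type arrays alone without control 3, with fewer degrees of freedom, gave 0 calls. In the simulated wild type contrast 95 of 268 calls were false. That simulation kept control 3 in the spread and held no pairing, so its false share need not hold for the 840.

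Of those 840 probes, 401 were higher (303 genes) and 439 lower (336 genes). The same fit without control 3 called 5074 probes after siPRMT1 in AE9a cells, against 3913 with all 12 arrays. Shared with those 5074 were 244 higher and 285 lower, against 34 and 41 for independent lists, and 8 and 5 were called in opposite directions. PRMT1 was then at -0.29 ± 0.14 (adjusted p = 0.293), and Pearson's r of the effects between the lines, across probes, was 0.473.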

How the results depend on the processing

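The filters on the olfactory receptor level, the block in wild type arrays, the fits without both number 3 arrays and the fits on wild type arrays alone with a block or without control 3 were chosen after seeing the data. Of 7800 values of 330 named genes and other single results under the alternatives, 7513 kept direction and side of the threshold, 236 lost their call, 39 gained one and 12 reversed, all without a call. Of 954 values of 37 list calls, 875 kept the call and 79 lost it.

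After siPRMT1 in AE9a cells 3913 probes were called, against 7101 with array weights, 6570 with only the arrays compared and 6091 with a block in wild type arrays. Stricter thresholds gave 1807 at an adjusted p of 0.01 and 1876 with a fold change of at least 1.5. Leaving out 1 array gave 2086 to 5074. For the difference between lines 260 became 473 without an intensity trend, 455 with weights, 402 with the replicate number as a block, 1241 with a block in wild type arrays and 65 at an adjusted p of 0.01, with 83 to 349 when 1 array was left out. For siPRMT1 in wild type cells 0 became 14 with a block in wild type arrays and 427 without both number 3 arrays, and 0 to 840 when 1 array was left out, with 840 without control 3 and 0 without any other array. Between the lines, 7555 under control siRNA became 4917 at 0.01 and 3754 at 1.5-fold, and 7002 under siPRMT1 became 4525 and 3561. Leaving out 1 array gave 5818 to 7646 and 5479 to 7994. Stricter thresholds lower counts by construction; for the other settings the cause was not tested.

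PRMT1 in AE9a cells ranged from -0.688 to -0.554 when 1 array was left out, with adjusted p up to 0.0842. The estimated correlation called 0 of 145 list tests, against 37, and leaving out 1 array gave 34 to 45 calls.

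The 12 reversals concern values that passed no test. ID1 between the lines under control siRNA was 0.022 under median scaling, 0.112 with weights and 0.036 without both number 3 arrays, and ran from -0.445 to 0.238 when 1 array was left out. The difference of the RUNX1 effect was -0.006 without both number 3 arrays and ran from -0.016 to 0.246. After siPRMT1 in wild type cells ID1 ran from -0.192 to 0.491, CDKN1A from -0.342 to 0.649 and RUNX1T1 from -0.054 to 0.006. EGR1 ran from -0.484 to 0.216 after siPRMT1 in AE9a cells and from -0.611 to 0.088 between the lines under siPRMT1. The cause was not tested.

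A block by BeadChip was not run because chips are not named, and a detection filter and neqc were not run because the table used here holds no detection p-values. Signal over background limits the rest: 46.0% of probes lay above the olfactory receptor level on at least 3 arrays.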

Other observations

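The metallothionein genes were picked after their values were seen, and the test on them was written before its result.

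Of 7 measured metallothionein genes, which bind zinc and copper, 6 fell after siPRMT1 in AE9a cells, with a median of -1.96: MT2A, MT1X, MT1E (-1.98 ± 0.13), MT1G (-1.96 ± 0.14), MT1H (-1.63 ± 0.09) and MT1F (-0.97 ± 0.12). In wild type cells 0 of 7 passed (median -0.05), and 5 differed between the lines. MT1G, 1 of those 5, was not above the olfactory receptor level in wild type siPRMT1 arrays, so a fall there may be hidden. Lower levels in wild type cells leave less room for a fall, and the share of this in the differences was not tested. In AE9a controls 6 stood above wild type controls, with a median of 2.91, MT1X by 3.83 and MT1G by 3.65, and under siPRMT1 5 did. A link with the stress response genes could not be told apart from no link: over the 12 arrays Pearson's r of the mean deviations from the group means was 0.49 (permutation p = 0.106) and Spearman's rho 0.34 (permutation p = 0.277), and r without the 2 farthest arrays was 0.45. The permutations exchanged arrays freely between groups, although deviations within a group are tied through its mean and wild type arrays varied more. Both permutation p-values are therefore only a rough guide. Whether metal in the culture medium differed was not tested.

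Of the lists in this paragraph, the first 8 had no camera call in any contrast with all 12 arrays. After siPRMT1 in AE9a cells p53 target genes fell in 5 of 17 and rose in 2 (adjusted p = 0.113), G1/S genes rose in 5 of 30 and fell in 1 (0.276), and cytosolic ribosomal proteins rose in 7 of 67 and fell in 6 (0.664). Apoptosis regulators fell in 5 of 29 and rose in 1 (0.444), JAK-STAT5 genes fell in 3 of 24 and rose in 1 (0.919), NF-kappaB genes rose in 3 of 17 and fell in 1 (0.748), interferon-stimulated genes fell in 1 of 33 (0.967) and megakaryocyte genes rose in 2 of 22 and fell in 2 (0.981). Among reported AML1-ETO targets 1 of 16 activated genes rose and 0 fell (0.908), and 2 of 14 repressed genes fell and 0 rose (0.559); hemoglobin chains had 1 of 9 higher and 1 lower (0.921), and progenitor genes 2 of 14 higher (0.2). Markers of B cells had 1 of 7 lower (0.967), T and NK cell markers 0 of 9 (0.902), epithelial and fibroblast markers 1 of 13 higher (0.748) and granulocyte and monocyte markers 0 of 15 (0.947). The B cell call, CD37 (-0.19), was lost without any AE9a array (adjusted p up to 0.188), with no filter (0.0956), no background correction (0.0554), no intensity trend (0.0678) or the replicate number as a block (0.0714), among other settings. The interferon-stimulated gene that fell, IRF9, both hemoglobin chains, HBD and HBQ1, and both repressed targets, NFE2 and SERPINB1, lost their calls without AE9a siPRMT1 3 (0.0676, 0.0656, 0.0859, 0.0883 and 0.105). So did both progenitor genes, LMO2 (0.181) and RUNX1 (0.21); LMO2 was also lost without AE9a controls 1, 2 and 3 in turn (0.112, 0.0925 and 0.0924), without AE9a siPRMT1 2 (0.0542), with the submitters' values (0.0616) and with no filter (0.0591).

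Between AE9a and wild type cells under control siRNA, interferon-stimulated genes went both ways, with 6 of 33 higher and 10 lower (adjusted p = 0.646): IFITM3 was 3.36 ± 0.13 higher and IFI35 was at -1.22. Arginine methyltransferases and partners were lower in 6 of 11 and higher in 1 (0.0502), NF-kappaB genes lower in 7 of 17 and higher in 2 (0.0981) and p53 targets higher in 7 of 17 and lower in 2 (0.089). G1/S genes were higher in 8 of 30 and lower in 4 (0.137), ribosomal proteins lower in 14 of 67 and higher in 7 (0.174), apoptosis regulators higher in 6 of 29 and lower in 3 (0.271), JAK-STAT5 genes lower in 4 of 24 and higher in 1 (0.612) and megakaryocyte genes higher in 5 of 22 and lower in 2 (0.748). Heme genes had 7 of 22 higher and 5 lower (0.407), immediate early genes 4 of 25 and 3 (0.973), with JUN at 2.59. B cell markers had 2 of 7 higher (0.752), T and NK cell markers 1 of 9 lower (0.908; CD3D, lost without wild type control 2 (0.106) or 3 (0.103) or any AE9a control (0.0726, 0.078 and 0.0812) and with no intensity trend (0.0512)), epithelial and fibroblast markers 3 of 13 higher and 4 lower (0.6) and granulocyte and monocyte markers 1 of 15 higher and 4 lower (0.538).

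For the other contrasts the splits of 6 arrays number 10, too few for a share under 0.05. Within wild type cells the real split gave 0 calls, so 10 of 10 gave at least as many, and the highest other gave 433. That split parted 1 of the 3 same-numbered pairs, whereas the other splits that parted 3, like the real one, gave 0. In AE9a cells after siPRMT1 the real split gave 3913 and the highest other 0. Between the lines it was 7555 and 0 under control siRNA, and 7002 and 0 under siPRMT1. In each, 1 split gave as many. Every other split here mixes the compared groups, which puts their difference into the spread within groups. The counts of 0 therefore do not show what chance gives.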
